A study of Ovis aries with 2 samples.

How the data were processed

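Single-cell RNA libraries of sheep testis were compared, 1 from a control and 1 labelled ZEA with the number 0.75, whose unit the labels do not give. ZEA is the usual abbreviation of zearalenone, a Fusarium mycotoxin with oestrogenic activity; the labels do not spell it out, and they do not say whether animals or cultured tissue were exposed. Both libraries are labelled as testis at 8 months and were made with a 10x Genomics 3' gel bead kit (version V3), per the labels. This droplet assay tags each captured RNA molecule with a unique molecular identifier (UMI), so that reads copied from a molecule are counted once.

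The deposited matrices hold raw UMI counts per gene and barcode, not normalized; how the barcodes were chosen is not given in the sources used here. The submitters' processing notes name Cell Ranger 3.1.0 and STAR for both libraries. Per the file headers, the control matrix was written by Cell Ranger 5.0.0 and the ZEA matrix by Cell Ranger 3.1.0, so the software version and the group cannot be told apart. The genome build and annotation are not given in the sources used here. Both matrices list the same 27054 genes, of which 10636 have an identifier and no symbol; those genes were counted in every sum and are not named. The lowest total in either matrix was 500 UMIs per barcode.

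Cells were kept with at least 500 UMIs, at least 200 detected genes and at most 20% of UMIs from the 13 mitochondrially encoded genes. Doublets were called in each library with Scrublet as built into scanpy 1.11.5 (seed 0, automatic threshold) and left out. It marked 198 control barcodes (2.82%) and 1 ZEA barcode (0.0114%), so the caller has not worked in the ZEA library and doublets remain there. Kept were 6811 control and 8804 ZEA cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen with the library as batch key, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (igraph 0.11.9), with no integration of the libraries.

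The marker genes of 16 cell types, 23 gene lists, the rule for named genes and the first group of alternatives given here were fixed before the data were examined. The numerical criteria that turn marker levels into a cluster name were not: a single set was written after the clusters and their markers had been looked at, and no other set was tried. A cluster was named when the mean standardized level of a marker list was at least 1 and led the next list by 0.2, at least 3 of its markers were enriched (at least 20 CPM of the cluster sum and 1.5 times the other clusters), its leading 10 genes held no more markers of another type than of its own, and fewer than 3 of those 10 were mitochondrial or small RNAs. A cluster whose median depth times 3 was below that of its library, and with no own marker among its leading 10 genes, stayed unnamed. Macrophage and lymphocyte lists leading together gave the name leukocyte-like. Of 25 clusters, 19 were named and 6 were not. The depth rule is relative to each library, and so kept a shallow control cluster unnamed where a ZEA cluster of similar depth was named.

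Each group has 1 library, so no test between groups was made, and no p-value or standard error was computed. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals. Expression within a class is the sum of UMI counts over its cells, as CPM, the usual scaling of counts to a common total, with exact Poisson intervals. Ratios of ZEA to control are on the log2 scale with exact conditional binomial intervals. All intervals cover counting error only and not differences between animals. A count of 0 was set to 3 counts for a ratio. Classes with at least 50 cells in each library were compared. A gene entered with at least 50 UMIs in both sums together and detection in at least 5% of the class cells of 1 library. Against RNA released by other cells, the higher class value had to reach 25% of the gene's highest value over classes of at least 20 cells in that library. The vascular and interstitial classes of the control library have under 20 cells each and were not used for this. Genes of those cell types can thus fail the rule more readily where higher in the ZEA library, which favours list members lower there.

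Genes were named by this rule: per class, the 4 highest and the 4 lowest log2 ratios among genes with a symbol, at least 200 UMIs and a 2-fold difference; from each described list, 2 to 4 members with the largest absolute ratio; and a fixed set of testis genes in the class where each was highest among classes with at least 10 UMIs. In that set CYP17A1, AMH, INHBB, CLDN11 and PRM1 matched no symbol and are not analysed here, and 1 further gene of the set is not reported here. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched in 10 bins of mean expression, as a description of these libraries. Under the alternatives 1000 random lists were drawn. Lists with under 3 entering members have no median. Other genes named in the text, such as VWF, FATE1, FOS and JCHAIN, were chosen after their values were seen.

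The ratio, interval and list steps were tested on simulated class sums with 200 genes changed 4-fold. For round spermatid-like cells (8952 genes) 100% of raised and 98.0% of lowered genes passed the 2-fold rule, 0.491% of unchanged genes did, and 95.1% of intervals held the simulated value. For elongating spermatid-like cells (7758 genes) the shares were 100%, 100%, 1.84% and 96.0%. The list of raised genes lay at percentile 100 in both classes, and a list of unchanged genes at 4.40 in round and 78.1 in elongating cells. Counts were Poisson draws from a profile shared by the libraries, with no spread between cells and no free RNA rule. The intervals thus hold the value at about their set rate by design, and the simulation checks the calculation only.

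The first group of alternatives held at least 500 genes per cell, no mitochondrial filter, doublets kept, Leiden resolution 0.5, centring each gene within its library, scaling by the median of gene ratios, equal weight per cell, at least 200 UMIs per gene, no free RNA rule, and cells thinned to 500 UMIs. Chosen after seeing the data were shares of named cells only, cells with at least 2000 or 5000 UMIs, leaving out the 5% highest doublet scores of each library, and counting each unnamed cluster in its best-scoring class. The comparison of log2 ratios with spermatogonia-like cells, made only to weigh the software version, used genes with at least 30 UMIs there. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.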

Results

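The transcripts of single testis cells were counted in 2 droplet libraries of sheep at 8 months, 1 control and 1 labelled ZEA. The design text describes the study as one of damage to the testis by ZEA, so the comparison asks how the cell types and their expression differ between the libraries. The control library held 7030 barcodes with 53044981 UMIs and the ZEA library 8809 barcodes with 22148456. With 1 library per group, every difference below has no replicate check, and a difference between animals, tissue pieces or preparations cannot be told apart from a difference between treatments.

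Cells of the control library were deeper. The median kept cell had 4121 UMIs and 1526 genes in the control library, and 1405.5 UMIs and 819 genes in the ZEA library. Thinned to 500 UMIs per cell, which left out no kept cell, the medians were 387 and 380 genes. Mitochondrially encoded genes gave 0.253% of all UMIs in the control library and 1.12% in the ZEA library. Cells under 1000 UMIs made up 20.3% of kept control cells and 36.9% of kept ZEA cells.

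**Figure D1:**
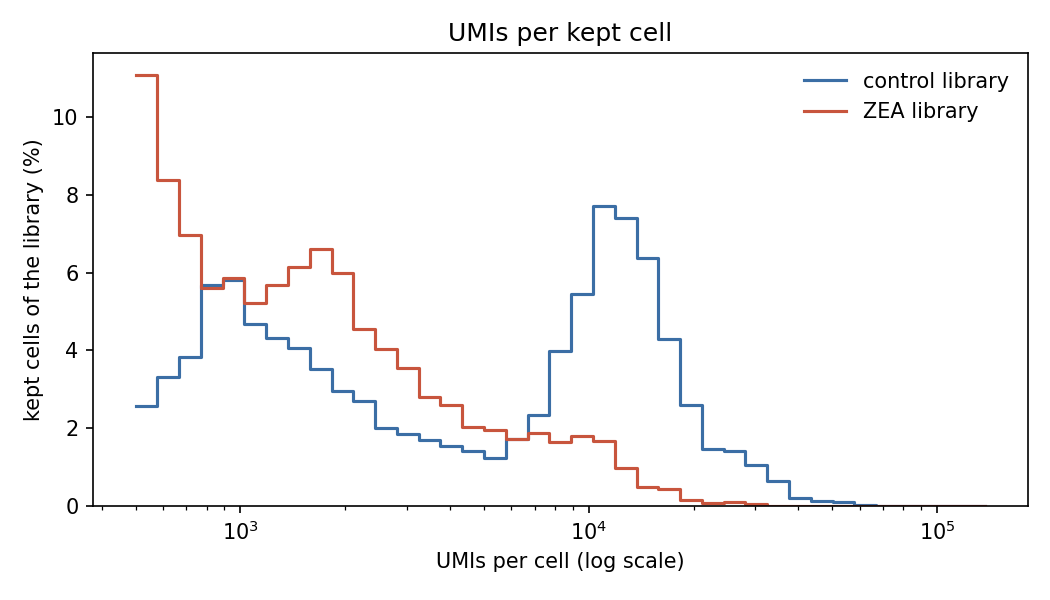
Share of kept cells (%, y axis) by UMIs per cell (x axis, log scale) in the control and ZEA libraries. The control library has a second mode of deep cells above 10000 UMIs, and the ZEA library piles up at the minimum of 500 UMIs.

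The control library was made up mostly of germ cells and the ZEA library of vascular, interstitial and spermatid cells. Endothelial-like cells, which line vessels, were 5 of 6811 control cells (0.0734%, 95% interval 0.0238 to 0.171) and 2259 of 8804 ZEA cells (25.7%, 24.7 to 26.6). Late spermatocyte-like cells, germ cells in meiosis, were 1155 control cells (17.0%, 16.1 to 17.9) and 6 ZEA cells (0.0682%, 0.0250 to 0.148). Sertoli-like cells, the nurse cells of the seminiferous tubule, were 112 control cells (1.64%, 1.36 to 1.98) and 1 ZEA cell (0.0114%, 0.000288 to 0.0633). The control cells of this class were shallow, with medians of 993 UMIs and 9.34% mitochondrial UMIs. Over all kept control cells these medians were 4121 UMIs and 0.0456%. Many of these classes come from clusters of nearly 1 library, so such a cluster may reflect that library and not a cell type alone.

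Apart from Sertoli-like cells, the other somatic classes were also more frequent in the ZEA library. Peritubular myoid-like cells, the contractile cells around the tubule, were 3 control cells (0.0440%) and 479 ZEA cells (5.44%), a ratio of 124 (42.0 to 601). Stromal fibroblast-like cells were 11 (0.162%) and 362 (4.11%), a ratio of 25.5 (14.1 to 51.5), and perivascular-like cells were 4 (0.0587%) and 339 (3.85%), a ratio of 65.6 (25.4 to 242). Of the somatic classes, leukocyte-like cells differed least, with 44 control cells (0.646%, 0.470 to 0.866) and 151 ZEA cells (1.72%, 1.45 to 2.01), a ratio of 2.65 (1.89 to 3.80). Among somatic cells, Sertoli-like cells made up 62.6% of 179 in the control library, and endothelial-like cells 62.9% of 3591 in the ZEA library.

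Within the germ line, spermatogonia-like cells, named after the dividing germ cells that precede meiosis, were rare in both libraries. They were 35 control cells (0.514%, 0.358 to 0.714) and 17 ZEA cells (0.193%, 0.113 to 0.309). They were 0.747% of germ cells in the control and 0.677% in the ZEA library. The ratio of their shares of all cells, 0.376, was 0.743 among cells with at least 2000 UMIs and 0.152 with doublets kept. The leading genes of this class include TEX11, of the meiotic list. No cluster was named early spermatocyte-like, so meiotic cells are not excluded from the class. Elongating spermatid-like cells were 2292 control cells (33.7%, 32.5 to 34.8) and 1034 ZEA cells (11.7%, 11.1 to 12.4). Round spermatid-like cells were 1203 control cells (17.7%, 16.8 to 18.6) and 1455 ZEA cells (16.5%, 15.8 to 17.3). The shares of both spermatid classes depend on which clusters were named. Unnamed cluster 0, whose best-scoring list was that of round spermatids, held 21.7% of control and 1.01% of ZEA cells; counting each unnamed cluster in its best class gave a round spermatid-like ratio of 0.445 in place of 0.936 and an elongating spermatid-like ratio of 0.646 in place of 0.349. Unnamed clusters together held 28.6% of control and 30.7% of ZEA cells.

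**Figure D2:**
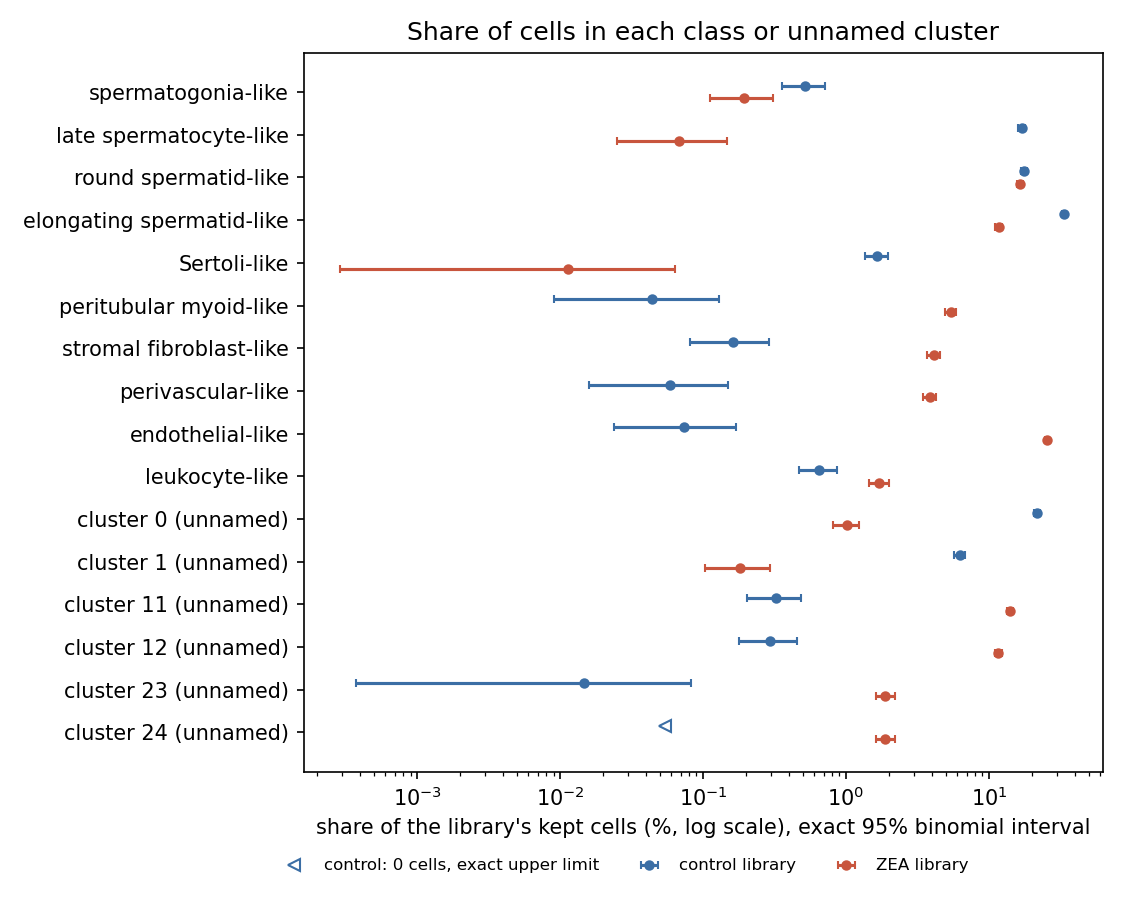
Share of each library's kept cells (%, x axis, log scale) in each class or unnamed cluster (y axis), with exact 95% binomial intervals that cover counting error only. Endothelial-like cells lie at 0.0734% in the control and 25.7% in the ZEA library, and the open triangle marks the limit that a count of 0 allows.

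Marker sums over all kept cells, which do not use the clusters, went the same way for vessels and muscle. Endothelial markers summed to 5.57 CPM (4.94 to 6.26) in the control and 1312 CPM (1297 to 1327) in the ZEA library, and peritubular myoid markers to 25.4 CPM (24.0 to 26.8) and 1893 CPM (1874 to 1911). Late spermatocyte markers summed to 4723 CPM in the control and 2221 CPM in the ZEA library, a log2 ratio of -1.09. This difference is far smaller than that of the late spermatocyte-like share, which was 249 times higher in the control library. The Sertoli list summed to 173 CPM (169 to 177) and 169 CPM (164 to 175), while its members FATE1 and FSHR, the receptor for follicle-stimulating hormone, had 21 and 14 UMIs in the control library and 0 in the ZEA library, and its member CITED1, a transcription cofactor, had 2.99 CPM (2.53 to 3.51) in the control and 3.21 CPM (2.5 to 4.04) in the ZEA library. For leukocytes, whose share was higher in the ZEA library, the lists parted. Macrophage markers summed to 882 CPM (874 to 890) in the control and 682 CPM (672 to 693) in the ZEA library. T or NK lymphocyte markers summed to 4.26 CPM (3.71 to 4.87) and 12.6 CPM (11.2 to 14.2). Against the macrophage sum, its member C1QA had 2.71 CPM (2.28 to 3.21) in the control and 18.2 CPM (16.5 to 20.1) in the ZEA library. Its member CD163 had 6 and 15 UMIs. The other members of that list are not given singly, so no direction of macrophages is read from the sum. Spermatogonia markers summed to 39.3 CPM (37.6 to 41.1) in the control and 39.1 CPM (36.6 to 41.8) in the ZEA library, unlike the share. The members of this list were mixed. TKTL1 had 9.03 CPM in the control and 4.56 CPM in the ZEA library, UCHL1 12.2 and 5.10 CPM, and STRA8 1.37 and 0.587 CPM. KIT went the other way, with 2.16 and 5.19 CPM. The equal sum is therefore not read against the lower share. Spermatid markers were also counted in other cells. Elongating spermatid markers reached 24.1% of their own class level in control Sertoli-like cells, 32.2% in control and 24.8% in ZEA leukocyte-like cells, and 8.82% in ZEA endothelial-like cells.

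**Figure D3:**
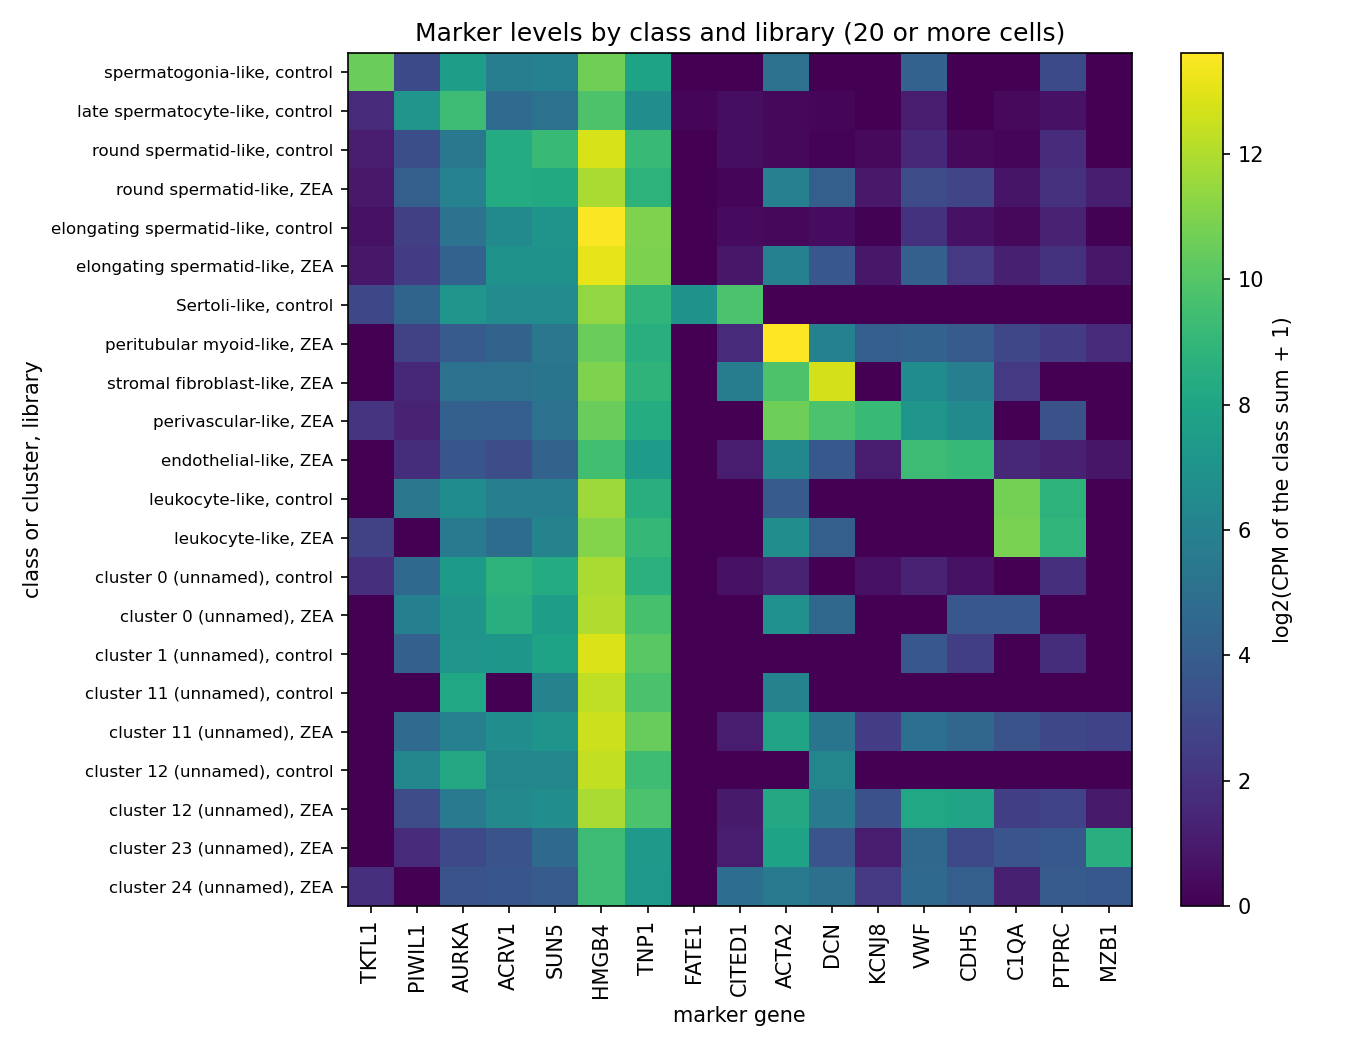
Marker level, log2 of CPM of the class sum plus 1 (colour), of named genes (x axis) in each class or unnamed cluster with at least 20 cells in a library (y axis). The spermatid gene HMGB4 is detected in every class, while the endothelial genes VWF and CDH5 peak in ZEA endothelial-like cells.

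The steroidogenesis list, with 12 genes in the files, summed to 133 CPM in the control and 544 CPM in the ZEA library over all kept cells, of which INSL3, STAR, CYP11A1 and HSD3B1 made up a small part. Its member FDX1, an electron carrier of steroid synthesis, had 131 CPM (125 to 136) in control and 101 CPM (92.9 to 110) in ZEA round spermatid-like cells. INSL3, a peptide hormone of Leydig cells, had 0 UMIs in the control library (up to 0.0731 CPM) and 268 in the ZEA library (12.1 CPM, 10.7 to 13.6), of which 191 lay in 3 of the 166 cells of unnamed cluster 24. STAR, which carries cholesterol into mitochondria for steroid synthesis, had 1 control UMI and 50 ZEA UMIs, 41 of them in 2 cells of that cluster. CYP11A1, which makes the first steroid from cholesterol, had 2.48 CPM (2.06 to 2.95) in the control and 4.11 CPM (3.31 to 5.05) in the ZEA library; in elongating spermatid-like cells, where it was highest, the values were 5.86 CPM (4.74 to 7.15) and 9.66 CPM (6.12 to 14.5). HSD3B1, which makes progestogens, had 0 and 5 UMIs. The oestrogen receptor ESR1 had 3 and 7 UMIs.

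Other testis genes fixed in advance are given for the class where each was highest. INHA, a subunit of the hormone inhibin, had 161 CPM (103 to 239) in control Sertoli-like cells, and 54 control and 10 ZEA UMIs over all cells. UCHL1, a ubiquitin hydrolase of spermatogonia, had 16 UMIs in control (59.2 CPM, 33.8 to 96.1) and 1 in ZEA (9.01 CPM, 0.228 to 50.2) spermatogonia-like cells. These intervals overlap, and over all kept cells UCHL1 had 614 and 113 UMIs. SYCP3, of the meiotic chromosome axis, had 17 UMIs in control spermatogonia-like cells (62.9 CPM, 36.6 to 101). In ZEA spermatogonia-like cells it had 0 UMIs (up to 33.2 CPM). KIT, a receptor of differentiating spermatogonia, had 2.16 CPM in the control and 5.19 CPM in the ZEA library over all cells, and was highest in unnamed cluster 12, with 15 ZEA UMIs and 0 control UMIs. ACRV1, an acrosome protein, was highest in cluster 0, with 438 CPM (409 to 468) in control and 388 CPM (267 to 545) in ZEA cells. TNP1, which replaces histones in spermatids, had 2010 CPM (1989 to 2032) in control and 1919 CPM (1864 to 1976) in ZEA elongating spermatid-like cells.

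In round spermatid-like cells, the median log2 ratio of ZEA to control of genes of the meiotic chromosome axis and recombination lay above its random lists, and that of genes of the spermatid chromatin, acrosome and tail below, each under some settings and not under others. The compared cells came from different clusters: mostly 4 and 6 in the control library (524 and 649 cells), and 19 and 21 in the ZEA library (1038 and 409 cells), with median depths of 13352 and 1260 UMIs over the class. The sums weigh cells by their UMIs, and the ZEA medians were 949 in cluster 19 and 9764 in cluster 21. A different mix of cells within the class was not tested, and cannot be told apart from changed expression within a cell type. The median log2 ratio over the 6174 genes that entered was 0.26, and scaling by the median of gene ratios lowered all values by 0.37. The 13 meiotic genes had a median log2 ratio of 0.78, at percentile 98.3 of random lists. SYCP1, of the synaptonemal complex, had 38.9 control and 205 ZEA CPM (log2 ratio 2.40, 2.26 to 2.54), SMC1B, a meiotic cohesin, 33.7 and 93.5 CPM (1.47, 1.30 to 1.64), and SYCP2 94.1 and 219 CPM (1.22, 1.11 to 1.32). The list median was 0.41 at percentile 98.5 when scaled by the median of gene ratios and 0.93 at percentile 99.9 with equal weight per cell. It lay inside the middle 95% of random lists under 4 other settings: 0.75 at percentile 96.3 after thinning to 500 UMIs, 0.65 at percentile 95.4 with at least 200 UMIs per gene, 0.65 at percentile 95.9 with no free RNA rule, and 0.70 at percentile 95.8 in cells with at least 5000 UMIs.

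The 23 spermatid genes had a median log2 ratio of -0.35, at percentile 1.10. TSSK6 and TSSK1B, kinases of spermatids, had log2 ratios of -1.87 (-2.32 to -1.45) and -1.13 (-1.19 to -1.08), and GAPDHS, the glycolytic enzyme of the sperm tail, -0.93 (-0.99 to -0.88). ZPBP2, an acrosome protein, went the other way at 1.13 (0.97 to 1.29). With equal weight per cell this list's median was -0.15, at percentile 40.5, and after thinning -0.14, at percentile 58.4; in cells with at least 5000 UMIs it was -0.34, at percentile 0.70. The extracellular matrix list, with 5 members, had a median of -0.67 at percentile 1.29, with MMP2, a matrix protease, at -1.94 and VCAN, a matrix proteoglycan, at 1.65. This placement was lost with no free RNA rule (8 members, -0.19 at percentile 4.80) and in cells with at least 5000 UMIs (6 members, -0.53 at percentile 2.60), both inside the middle 95% of random lists. That rule held matrix genes higher in the ZEA library against ZEA stromal fibroblast-like cells, among other classes. The control class of that name has 11 cells and was not used, so the rule favours members lower in the ZEA library. No direction is read from this list.

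Stress lists in round spermatid-like cells lay inside the middle 95% of random lists, except the unfolded protein response after thinning and heat shock with no free RNA rule. The unfolded protein response list (7 genes) had a median of 0.51 at percentile 88.9, with the chaperone HSP90B1 at 698 control and 2172 ZEA CPM (log2 ratio 1.64, 1.60 to 1.67); thinned to 500 UMIs, 6 genes of this list had a median of 1.12 at percentile 99.9. The DNA repair list (10 genes) had 0.72 at percentile 92.4, with TP53BP1, a double-strand break sensor, at 2.20, the kinase ATM at 1.98 and CHEK2, a checkpoint kinase, at -1.08. The antioxidant list (7 genes) had -0.03 at percentile 23.5, the apoptosis list (4 genes) 0.48 at percentile 58.5, and the heat shock list (3 genes) 0.06 at percentile 49.1; with no free RNA rule, 6 genes of the heat shock list had a median of 1.15 at percentile 99.4. The antioxidant, heat shock and glycolysis medians, all near 0, changed sign under alternatives. Glycolysis genes had members both ways, GPI, which converts glucose-6-phosphate, at -2.38 and LDHC, the lactate dehydrogenase of germ cells, at 1.45.

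Among genes with a symbol and at least 200 UMIs, the largest differences in round spermatid-like cells were in genes of several functions. AKAP9 (ENSOARG00000017010), a scaffold protein of the centrosome, had 11.2 control and 120 ZEA CPM (log2 ratio 3.42, 3.19 to 3.65), DNAJC13, an endosomal co-chaperone, 3.35 (2.98 to 3.74), HERC2, a ubiquitin ligase, 3.26 (2.87 to 3.67), and SHTN1 3.19 (2.83 to 3.56). Lowest were PLB1 (ENSOARG00000019515), a phospholipase, with 50.4 and 2.62 CPM (-4.27, -5.11 to -3.54), the melatonin receptor MTNR1A (ENSOARG00000008287) with 76.5 and 4.37 CPM (-4.13, -4.76 to -3.56), VAT1L at -3.03 (-3.33 to -2.74) and GRXCR2 at -2.88 (-3.96 to -1.97).

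In elongating spermatid-like cells, the median of glycolysis genes lay below its random lists, except in cells with at least 5000 UMIs, and MTNR1A, PLB1 and VAT1L were again among the lowest genes with a symbol and at least 200 UMIs. Control cells came mostly from clusters 2, 3 and 7 (936, 525 and 782 cells) and ZEA cells from cluster 14 (938 cells). A different mix of cells within the class was not tested here either. The median log2 ratio over 3754 genes was 0.16, and scaling by the median of gene ratios lowered all values by 0.22. The 8 glycolysis genes had a median of -0.51 at percentile 1.44, with GAPDHS at -1.13 (-1.19 to -1.06), GPI at -0.89 (-0.98 to -0.80), HK2, a hexokinase, at -0.88 (-1.20 to -0.58) and PGAM2, a phosphoglycerate mutase, at -0.59 (-0.67 to -0.52). After thinning the list median was -1.06. In cells with at least 5000 UMIs, of which 54 were ZEA cells, it was -0.27 at percentile 4.80, inside the middle 95% of random lists, with GAPDHS at -0.36. Of those deep cells, 40 ZEA cells and 753 of the 1080 control cells lay in cluster 7. The smaller glycolysis difference there thus came with a shared cluster as well as with depth. The spermatid list (19 genes) had -0.12 at percentile 19.6, and 0.13 in cells with at least 5000 UMIs; its member PRM3, a protamine family gene, had 723 control and 1862 ZEA CPM (1.37, 1.32 to 1.42).

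The unfolded protein response list had 3 entering members in elongating spermatid-like cells and a median of 0.78 at percentile 96.3, with HERPUD1, of protein degradation from the endoplasmic reticulum, at 1.28 (1.14 to 1.42). This median was 1.34 at percentile 99.1 after thinning, 0.19 over 12 members at percentile 68.5 with no free RNA rule, and -0.08 in cells with at least 5000 UMIs, so its size and sign depend on the genes and cells used. The cells with at least 5000 UMIs differ in cluster as well as in depth: 40 of the 54 ZEA cells lay in cluster 7, as did 753 of the 1080 control cells. Highest of the genes with a symbol and at least 200 UMIs were STX4, a membrane fusion protein, at 2.62 (2.21 to 3.02), ADAM29, a testis metalloprotease-like protein, at 2.41 (2.27 to 2.55), POMT1, a protein mannosyltransferase, at 2.34 (1.97 to 2.71) and CNTLN, a centriole protein, at 2.12 (1.99 to 2.26). Lowest were MTNR1A, with 632 control and 2 ZEA UMIs (-5.52, -8.57 to -3.66), PLB1 at -2.99 (-3.47 to -2.54), SV2A, a vesicle protein, at -2.98 (-4.87 to -1.61) and VAT1L at -2.56 (-2.86 to -2.27).

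**Figure D4:**
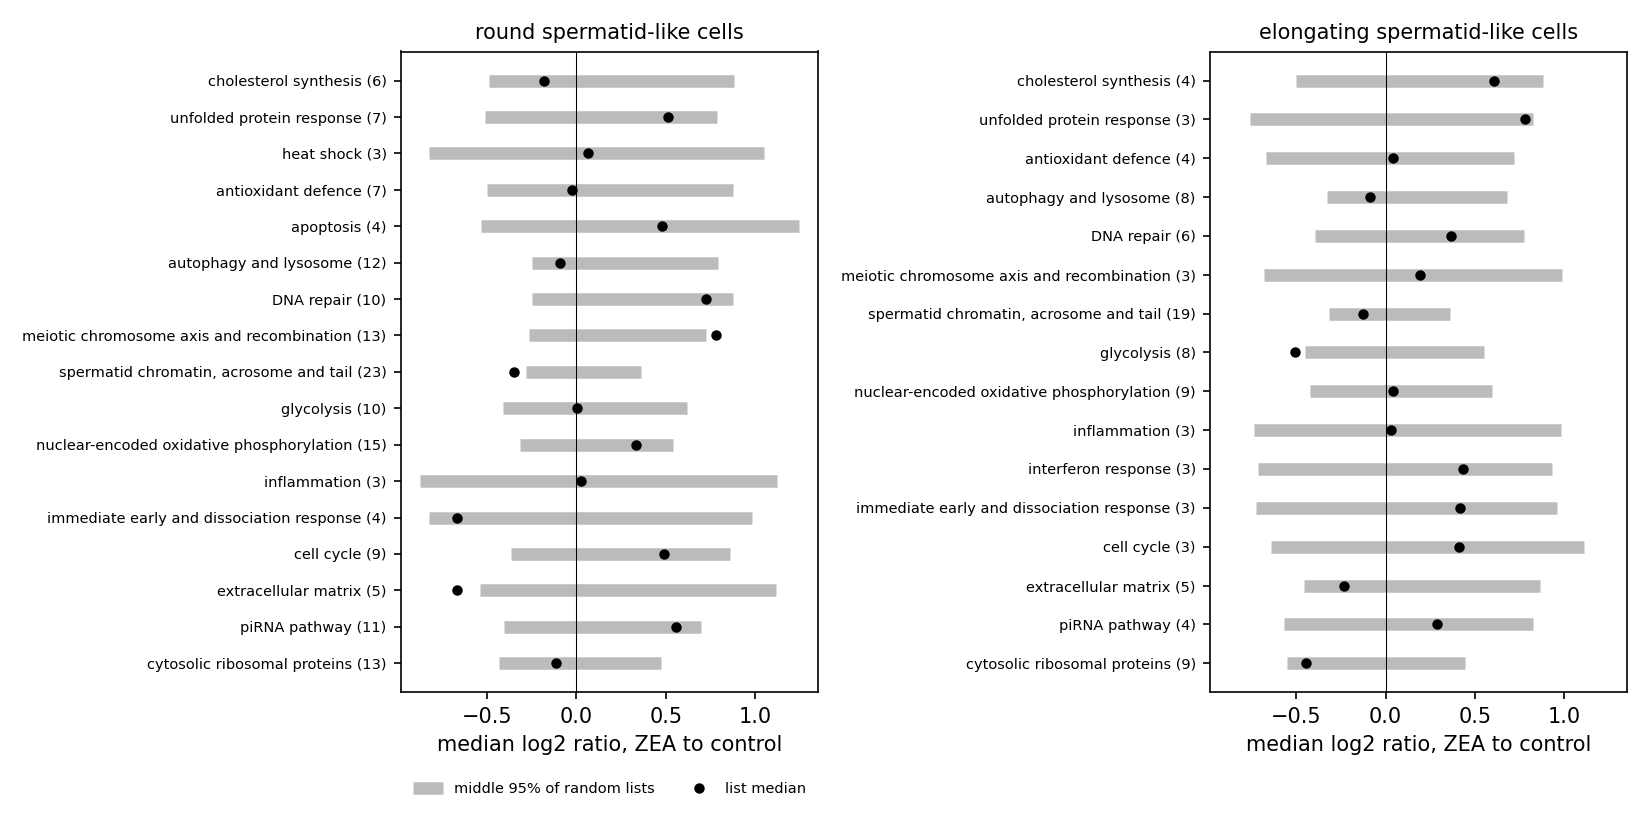
Median log2 ratio of ZEA to control (x axis) of each gene list with at least 3 entering members (y axis, members in brackets) in round and elongating spermatid-like cells, with the middle 95% of 10000 matched random lists as grey bars. The meiotic list in round cells lies above its bar at 0.78, and the spermatid and matrix lists in round cells and the glycolysis list in elongating cells lie below theirs.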

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

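Of the tests in this part, the thinning test in round spermatid-like cells and the correlation with spermatogonia-like cells were written down before their results were seen; all others were chosen only after related values had been seen.

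A pair of unnamed clusters lay outside the compared classes and were almost absent from the control library. Cluster 23 held 166 ZEA cells and 1 control cell. Its leading genes include JCHAIN and MZB1, known from antibody-secreting cells, for which no marker list had been fixed, so the cluster keeps no name; JCHAIN had 775 CPM there. Cluster 24 held 166 ZEA cells and 0 control cells, which allows a control share of up to 0.0541%.

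Vascular and interstitial cells were 0.338% of control and 39.1% of ZEA cells. Shallow barcodes kept by cell calling are argued against as the whole cause, since among cells with at least 2000 UMIs the endothelial-like share was still 467 times higher in the ZEA library (182 to 1716). Loss of germ cells alone would raise every somatic class alike. The Sertoli-like share was instead lower in the ZEA library, with a ratio of 0.00691 (0.000173 to 0.0393), which argues against such a loss as the only cause. Among cells with at least 2000 UMIs the ratio was 0.0897, from 15 control cells and 1 ZEA cell. Most control cells of this class were shallow, which limits this argument. So does the Sertoli marker sum over all kept cells, nearly equal at 173 CPM in the control and 169 CPM in the ZEA library. Its members FATE1 and FSHR had 0 UMIs in the ZEA library. The leukocyte-like ratio of 2.65 (1.89 to 3.80) and the endothelial-like ratio of 350 (150 to 1077.5) were not alike either. A different part of the testis or another dissociation stays open. That 4 of the 4 vascular and interstitial classes were higher restates the pattern, and of the classes inside the tubule the round spermatid-like ratio, which changes with the naming of clusters, was 0.936 (0.866 to 1.01). The treatment, the animal and the piece of tissue or its dissociation cannot be told apart, because each is represented by 1 library per group.

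Spermatids of the libraries fell into different clusters. In round spermatid-like cells, 67.8% of the genes with a 2-fold difference were higher in the ZEA library, but 35.1% when scaled by the median of gene ratios; in elongating spermatid-like cells these shares were 68.9% and 42.5%. In round spermatid-like cells thinned to 500 UMIs, 60.8% of the genes with a 2-fold difference kept one in the same direction, or 66.0% of those that still had at least 10 UMIs; 20.03% kept it and also met the entry rules again. In cells with at least 5000 UMIs 88.9% kept it, and 371 of the 408 ZEA cells were still in cluster 21, with 1 of the 1147 control cells. Cells kept their full-depth clusters in both checks and were not clustered again. Thinning mainly changes the weight of each cell and adds counting error, so it decides little about depth. Deep cells of the libraries still lay in different clusters, which argues against depth as the whole cause for those cells only. Free RNA of somatic cells was weighed on genes 2-fold higher in the ZEA library with neither the free RNA rule nor that scaling applied. In ZEA round spermatid-like cells endothelial markers stood at 1.04% of their own class level, the highest of 3 somatic lists. With that percentage of each gene's highest level over the ZEA somatic classes taken off, 91.6% of these genes were still 2-fold higher, which argues against free somatic RNA as the whole cause for these genes. In elongating spermatid-like cells 84.5% were, with 1.43% taken off, but the depth checks part: after thinning, 84.4% of the genes with a 2-fold difference kept it, or 85.3% of those that still had at least 10 UMIs, and 39.9% kept it and also met the entry rules again, while in cells with at least 5000 UMIs 33.8% kept it. Of the 54 ZEA cells among these, 40 lay in cluster 7 with most of the control cells, so the cluster changed together with the depth, and depth and the group cannot be told apart there. A factor acting on the same genes in every cell, such as the software version that differs between the files or a variant of 1 animal, may contribute: log2 ratios in round spermatid-like cells correlated with those in spermatogonia-like cells at Pearson 0.211 and Spearman 0.219 across 1472 genes, which are not independent replicates, and with 35 and 17 spermatogonia-like cells this decides nothing. The treatment and a different mix of cells within a class stay open and untested.

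Shallow ZEA barcodes formed unnamed clusters 12 (1028 cells, median 684 UMIs) and 11 (1236 cells, median 601 UMIs). The profile of cluster 12, led by mitochondrial genes, correlated with the summed ZEA library at 0.978 across 7817 genes. The highest of 7 named classes stood at 0.870. Droplets that hold mostly free RNA would give such a value. Unnamed cluster 23, with a median of 3817.5 UMIs in its ZEA cells, also lay above every named class, at 0.901. The measure therefore does not single out free RNA. Cluster 11, led in part by small RNAs, correlated at 0.844, below 3 of the named classes. That value alone does not tell free RNA from shallow germ cells. Its ZEA barcodes had a median mitochondrial share of 0%, as had ZEA round and elongating spermatid-like cells. The share was 1.12% of all kept ZEA UMIs, and its median was 2.27% in ZEA cells of cluster 12. For many cluster 11 barcodes this argues against mostly free RNA, if such RNA has the makeup of the whole library. No biological explanation was tested for these clusters.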

How the results depend on the processing

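No paired analysis was possible because each group has 1 library. The alternatives described as added were chosen after seeing the data. Of 123 ratios of shares under alternatives, 94 stayed within the counting interval of the reported ratio; the cause of the others was not tested.

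Round spermatid-like ratios of 0.936 became 0.510 with at least 500 genes per cell, 0.466 with no mitochondrial filter, 1.06 with doublets kept and 0.304 at Leiden resolution 0.5, and in the added alternatives 0.630 with at least 2000 UMIs and 0.445 with unnamed clusters in their best class. No direction is read from this class. Elongating spermatid-like ratios of 0.349 became 0.292 with doublets kept, 0.313 at resolution 0.5 and 0.646 with best classes. Both spermatid classes together, 0.551, gave 0.427, 0.383, 0.507 and 0.310 under the planned filters in that order, and 0.484 with at least 2000 UMIs. Germ classes together, 0.415, gave 0.323 with at least 500 genes, 0.289 with no mitochondrial filter, 0.245 at resolution 0.5, 0.350 with at least 2000 UMIs and 0.451 with best classes. Spermatogonia-like, 0.376, gave 0.152 with doublets kept and 0.743 with at least 2000 UMIs. Late spermatocyte-like, 0.00402, gave 0.00137 with centring. Sertoli-like, 0.00691, gave 0.0897 with at least 2000 UMIs. Somatic classes together, 15.5, gave 27.3 with at least 500 genes, 21.4 at resolution 0.5, 63.9 with at least 2000 UMIs and 19.2 with best classes. Vascular and interstitial classes, 116, gave 228 with at least 2000 UMIs, and endothelial-like cells, 350, gave 102 with best classes. At resolution 0.5 the spermatogonia-like, perivascular-like and leukocyte-like classes were not named and gave no value.

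Requiring at least 500 genes raised the median depth to 6090 UMIs in the control and 1747 in the ZEA library. The median absolute log2 ratio over genes was 0.57 in round and 0.44 in elongating spermatid-like cells; in the latter it was 0.66 with equal weight per cell and 0.69 after thinning. Of 1820 log2 ratios of named genes under alternatives, 1315 stayed within their counting interval, 504 moved outside it, and 1 reversed: ATF6 in round spermatid-like cells was -0.43 after thinning. Of 184 list medians, 175 stayed within the spread of random lists around the reported median; the others include the autophagy list in elongating spermatid-like cells, 0.43 after thinning. A median within that spread can still lose its placement, as the spermatid list in round spermatid-like cells did at percentiles 40.5 with equal weight per cell and 58.4 after thinning; scaling by the median of gene ratios shifts every gene alike, and left that list at percentile 1.10 with a median of -0.72. Depth limits the comparison of elongating spermatid-like cells, of which 54 in the ZEA library had at least 5000 UMIs.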

Other observations

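The immediate early genes FOS and JUN were chosen after their values were seen, while the gene lists were fixed beforehand. The list of immediate early genes, which respond within minutes to stimuli that include tissue dissociation, summed to 161 CPM over 19 genes in the control and 5567 CPM in the ZEA library over all kept cells. FOS had 4.91 CPM in the control and 1358 CPM in the ZEA library, and JUN had 9.93 and 2349 CPM. FOS had 3858 CPM in ZEA peritubular myoid-like and 2431 CPM in ZEA endothelial-like cells. In leukocyte-like cells, the somatic class present in both libraries with the most balanced share, FOS had 1754 CPM in 44 control cells and 1447 CPM in 151 ZEA cells, and JUN had 1684 and 3239 CPM. In the 112 control Sertoli-like cells, which have 1 counterpart in the ZEA library, FOS had 0 UMIs (up to 24.7 CPM) and JUN 1 UMI.

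Ribosomal protein genes summed to 26226 CPM in the control and 83814 CPM in the ZEA library over all kept cells, and mitochondrially encoded genes to 2528 and 11213 CPM. In round spermatid-like cells the ribosomal list had a median log2 ratio of -0.12 over 13 genes, at percentile 27.4, and in elongating spermatid-like cells -0.44 over 9 genes, inside the middle 95% of random lists. With no free RNA rule, 33 genes entered and the signs turned, with 0.18 at percentile 80.4 in round and 0.03 at percentile 53.8 in elongating spermatid-like cells; in round spermatid-like cells with at least 5000 UMIs the median was 0.05 over 14 genes.

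No direction is read from the further lists, which lay within the range of their random lists. In round spermatid-like cells the medians were 0.49 for the cell cycle (9 genes) and -0.18 for cholesterol synthesis (6 genes). Medians of other lists there changed sign under at least 1 alternative: 0.56 for the piRNA pathway and 0.33 for nuclear-encoded oxidative phosphorylation were -0.41 and -0.29 after thinning, -0.67 for immediate early genes (4 genes) was 0.16 over 9 genes with no free RNA rule, -0.09 for autophagy and lysosome was 0.07 in cells with at least 5000 UMIs, and 0.02 for inflammation was -0.25 with equal weight per cell. Outside the middle 95% of random lists were the piRNA pathway with equal weight per cell (0.83 at percentile 98.4) and immediate early genes when scaled by the median of gene ratios (-1.04 at percentile 1.80).

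In elongating spermatid-like cells the medians were 0.61 for cholesterol synthesis (4 genes), 0.29 for the piRNA pathway (4 genes), 0.36 for DNA repair (6 genes) and 0.43 for the interferon response (3 genes). Others changed sign: 0.41 for the cell cycle (3 genes) was -0.32 over 9 genes with no free RNA rule and -0.45 in cells with at least 5000 UMIs, where 0.42 for immediate early genes (3 genes) was -0.14, 0.04 for oxidative phosphorylation was -0.08 and 0.04 for antioxidant defence was -0.27. Autophagy and lysosome had -0.09, and 0.37 with equal weight per cell; meiotic genes had 0.19 and inflammation 0.03, and -0.02 and -0.19 when scaled by the median of gene ratios. The extracellular matrix had -0.23, and 0.02 over 7 genes with no free RNA rule; it lay outside the middle 95% of random lists with equal weight per cell (-0.67 at percentile 1.5) and in cells with at least 5000 UMIs (-0.37 at percentile 1.30). The steroidogenesis, hormone response, Sertoli, contractile and mitochondrially encoded lists had under 3 entering members in both classes and have no median, as had the interferon list in round and the heat shock and apoptosis lists in elongating spermatid-like cells.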
